A study of Mus musculus with 8 samples.

How the data were processed

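Total RNA of cultured mouse cells was hybridized to Affymetrix 3' expression arrays, with 1 array per sample and 8 arrays in all. NIH3T3, a mouse embryonic fibroblast line, and B16F10, a mouse melanoma line, had been infected with virus carrying PGC7, also called Stella or Dppa3, a maternal and germ cell protein that protects DNA methylation in the early embryo. Arrays were put into 4 groups by their titles: NIH3T3 control (n = 1), NIH3T3 PGC7 (n = 3: clone 1, clone 2 and an uncloned mixture of clones), B16F10 control (n = 1) and B16F10 PGC7 (n = 3: clones 1 to 3). The genotype label of all 6 PGC7 samples gave a differing name, PGC8, and described every one of them as not yet cloned, so the groups were taken from the titles. Whether the controls had received an empty virus is not given in the sources used here, nor are hybridization dates, so line and array batch cannot be told apart. Whether a line's control and PGC7 arrays were hybridized together is not given either.

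The deposited values were intensity signals on a linear scale, 1 per probe set, made with MAS5 according to the submitters' processing notes, with a version and settings not given in the sources used here. The 4 deposited B16F10 columns had a trimmed mean, between percentiles 2 and 98, of 500.003 each. The NIH3T3 columns did not share such a mean: it was 177.97 in the control, 188.67 in the uncloned array, 143.45 in clone 1 and 159.17 in clone 2. The plan had been to keep the deposited scaling. After these means were seen, every array was instead multiplied to the B16F10 trimmed mean, by 2.81, 2.65, 3.49 and 3.14 for those NIH3T3 arrays and by 1 for B16F10, and the values as deposited became an added alternative. Signals below are these scaled signals in arbitrary units. The number of arrays limits the precision of all values.

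Signals were transformed as log2(signal + 9), where 9 is the rounded 25th percentile of all scaled values. Changes are given on that scale, which understates the change of probe sets with low signal. Of 45101 probe sets, 64 were control probe sets, and 19801 were removed because their mean log2 value was under the median of all values (signal 49.3) in both lines (4 arrays each). The remaining 25236 were tested. Probe sets were given gene symbols through the platform's annotation and matched by gene identifier to the annotation of assembly GRCm38.p6, with 34958 probe sets having 1 symbol, 932 several and 9211 none. The tested probe sets stood for 11643 genes.

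Tests were done in R 4.3.3 with limma 3.58.1. A model with 4 group means was fitted to all 8 arrays, and its moderated test, with an intensity-dependent variance prior, gave the change in each line and the difference between the lines (residual plus prior degrees of freedom, 8.50). The lone controls have no spread of their own and were assumed to vary like the PGC7 arrays. The model also assumed the same spread of a probe set in both lines. Change across both lines was tested with line as an additive term (9.19 degrees of freedom). All tests were two-sided, and a probe set was called at a Benjamini-Hochberg adjusted p under 0.05. The p-values measure only the spread between these samples. The clones and the uncloned culture of a line were treated as replicates, although cultures taken from the same infected population would not be independent. Probe sets at least 2-fold from the control in the same direction in all 3 PGC7 arrays of a line were counted without a test, and the same count was made with each PGC7 array in the control's place. The changes of the lines were correlated across probe sets, which are not independent replicates.

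Before the data were examined, 32 gene lists with 859 entries were written from textbook knowledge, of which 780 matched a measured gene, and the comparisons, tests, most alternatives and the rule for named genes were fixed. A gene was represented in the lists by its brightest tested probe set. The 28 lists with at least 5 tested genes were tested with limma's camera at an inter-gene correlation of 0.01, adjusted over the lists within a comparison. Lists are described with the number of members called over all tested probe sets and the number called when p was adjusted over the list alone, which for uncalled lists is given where it differs. The lists covered DNA methylation machinery, germline genes, X-linked germline genes, pluripotency genes, imprinted genes, interferon-stimulated genes, antigen presentation, cell cycle phases, p53 targets, mesenchymal genes, matrix proteases, metastasis suppressors, immediate early genes, YAP and TGF-beta targets, chemokines, growth factors, stress responses, hypoxia, cholesterol synthesis, housekeeping genes and markers of 9 cell types, besides Dppa3 itself.

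The named-gene rule took, among probe sets with 1 symbol, Dppa3 on every array, and then for each line the 12 genes with the largest rise and the 12 with the largest fall among those called and at least 2-fold the same way in all 3 PGC7 arrays. It also took up to 8 genes each way called across both lines with the same direction in all 6 PGC7 arrays, the 5 each way that differed most between the lines, and up to 4 members of each list per line, called members first. Some genes that the rule took are not described here. Any other gene is said to have been chosen after its values were seen.

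The alternatives fixed at that time were quantile normalization, pseudocounts of 1 and 49 (the median), no filter (45037 probe sets), a filter at percentile 75 (13385 probe sets), a model on 1 line only, a prior without the intensity trend, the mean of the lines' contrasts in place of the additive model, an estimated inter-gene correlation, the mean of a gene's probe sets, and leaving out each PGC7 array or, across both lines, each control. The values as deposited and a scaling of each line's arrays on their poly-A spike controls were added after the data were seen. Without a line's only control, the change across both lines comes from the other line alone. The counts of alternatives given for single genes leave out the prior without the intensity trend. Across both lines they also leave out the mean of the contrasts and the fits without a control. Chromosome regions were examined in 222 windows of 50 neighbouring genes against 200 shuffled gene orders.

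The procedure was tested on simulated data with this design. Of changes planted in 1 line, 29.9% were recovered at 2-fold and 77.6% at 4-fold for NIH3T3, and 26.9% and 56.7% for B16F10, with 7 false calls in each. For differences between the lines, 11.9% were recovered at 2-fold and 58.2% at 4-fold, with 10 false calls, and for changes across both lines 55.2% and 91.0%, with 5. A list planted at a log2 change of -1 was fitted at -0.98, and 0 other lists were called. The simulated noise was independent between genes and as wide in the controls as in the PGC7 arrays. The simulation therefore tests neither the held inter-gene correlation nor the assumed spread of the controls. No array was left out.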

Results

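The 8 arrays separated by cell line. Across tested probe sets the correlation between arrays of differing lines was 0.679 to 0.698. Within NIH3T3 it was 0.912 to 0.920 between the control and the PGC7 arrays and 0.962 to 0.978 among the PGC7 arrays. In B16F10 these values were 0.970 to 0.977 and 0.983 to 0.987. The melanocyte genes Tyrp1, Dct, Mlana and Pmel had signals of 21810, 22920, 20530 and 16290 in the B16F10 control and of 46.9, 31.9, 9.74 and 32.4 in the NIH3T3 control. The collagen genes Col1a2 and Col3a1 and the matrix proteoglycan gene Dcn, chosen after their values were seen, had 36060, 27080 and 13830 in the NIH3T3 control against 257, 7.97 and 13.8 in the B16F10 control. In the PGC7 arrays Col3a1 averaged 29440 in NIH3T3 and 12.9 in B16F10, and Mlana 3.94 and 23970, so both sets of markers went with the line labels.

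The poly-A spikes, added to the RNA before labelling, had a median log2 difference from the control of 0.58, 0.47 and 0.72 in B16F10 clones 1, 2 and 3 and of -0.28, -0.26 and -0.59 in the uncloned NIH3T3 array and clones 1 and 2. The hybridization controls, added afterwards, averaged 0.01 in NIH3T3 and 0.12 in B16F10. The 18S ribosomal RNA probe sets were above the control in all 6 PGC7 arrays, by 0.32 to 0.96 in NIH3T3 and 0.21 to 0.93 in B16F10. Scaling on the poly-A spikes moved the median change of all tested probe sets from -0.07 to 0.30 in NIH3T3 and from 0.02 to -0.60 in B16F10, and the values as deposited had a median of -0.20 in NIH3T3. Directions below are therefore relative to the average probe set of each array. The called named genes that passed the filter under these scalings kept their direction: 99, 95 and 100 of 100 in NIH3T3 under quantile normalization, the deposited scaling and the spike scaling, and 45 of 45 in B16F10 under each. In that order, 98, 83 and 80 in NIH3T3 and 37, 37 and 32 in B16F10 also kept their call. These genes were taken as called in the same data, which favours a kept direction.

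Dppa3 itself, read by probe set 1424295_at, was not called in either line over all tested probe sets. Its signal in B16F10 was 23.5 in the control and 70.0, 117 and 71.0 in clones 1, 2 and 3, a log2 change of 1.51 ± 0.58 (± SE, adjusted p = 0.27). The unadjusted p of that moderated test was 0.0307, which adjustment over its list of 1 gene leaves unchanged. In NIH3T3 the control had 69.8, the uncloned array 101, clone 1 29.7 and clone 2 55.4 (log2 -0.28 ± 0.58, adjusted p = 0.802). Across both lines the change was 0.62 (adjusted p = 0.55). Where the probe set lies relative to the transferred sequence is not given in the sources used here, so it could not serve as a check of the group labels.

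In NIH3T3, arrays labelled PGC7 had far lower signals than the control for pleiotrophin, osteoglycin, a type I collagen chain, periostin and thrombospondin, while other matrix genes such as Col3a1 and Dcn kept high signals. Of the fibroblast markers 12 of 26 fell and of the YAP and TGF-beta targets 10 of 18, both called lower as lists (adjusted p = 0.228 and 0.803 with an estimated correlation). A set of genes low or nearly silent in the control was strongly expressed, among them those for the alarmin cytokine Il33 and the transcription factor Mycn. Interferon-stimulated genes were lower and hypoxia and glycolysis genes higher as groups, though 0 of the 4 list calls in this line held with an estimated correlation (adjusted p = 0.228 to 0.871). In all, 3229 probe sets were called, 1634 higher (1071 genes) and 1595 lower (1033 genes). With the NIH3T3 arrays alone the number was 1151, against 2196 in B16F10 with its own arrays alone. It was 6133 without the uncloned array and 1999 without B16F10 clone 1, which enters the shared spread. At least 2-fold changes in all 3 PGC7 arrays were seen for 2168, with 972 higher and 1196 lower. The balance of directions went with the scaling: of the called, 50.6% were higher here, 37.7% as deposited and 74.7% on the spikes, and of those at least 2-fold, 44.8% here, 55.9% with quantile normalization and 72.5% on the spikes. With the uncloned array, clone 1 or clone 2 in the control's place, that count was 542, 288 and 383.

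**Figure D1:**
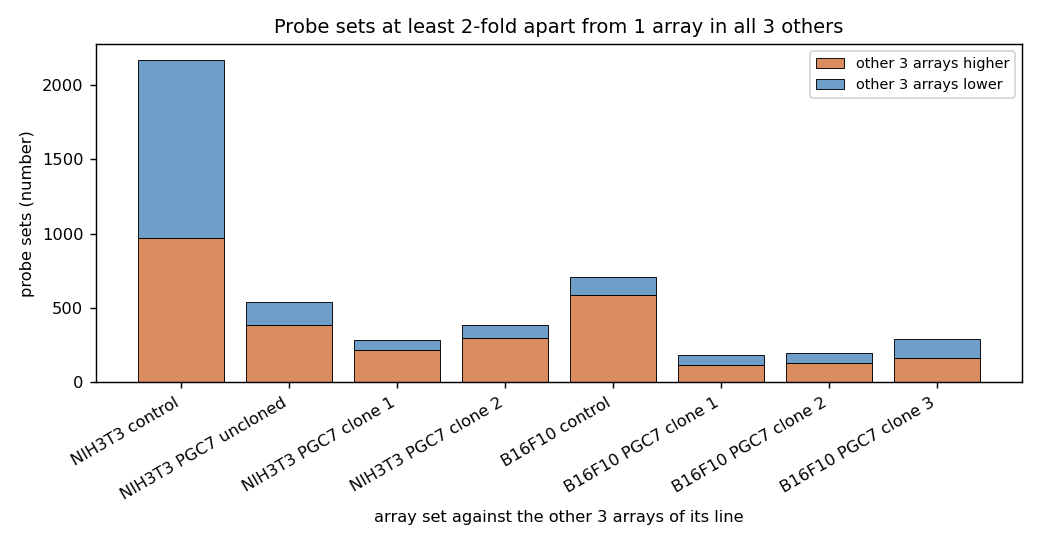
Number of tested probe sets (vertical axis) at least 2-fold apart from the array on the horizontal axis in all 3 other arrays of its line, as stacked bars of higher and lower probe sets for NIH3T3 and B16F10. Each line's control has the tallest bar.

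Il33 (1416200_at) rose from a signal of 6.13 to 7751 ± 4628 (mean ± SD of the PGC7 arrays), a log2 change of 8.81 ± 0.65 (adjusted p = 0.000199). Tcim, a regulator of transcription, rose by 7.78 ± 0.62 (1451415_at, signal 3.20 to 2692), and Mycn by 7.65 ± 0.25 (1425923_at, 64.0 to 14690 ± 1695). A second Mycn probe set, 1425922_a_at, had -0.82 (adjusted p = 0.553). Evi2a rose by 7.06, the G protein signalling regulator Rgs16 by 6.67 (5.51 to 2008 ± 1962), and the uridine phosphorylase gene Upp1 by 6.49 (62.7 to 6574). Further rises included the T-cell adaptor gene Fyb at 6.44, the semaphorin gene Sema7a at 6.03 (118 to 8502), Pi16 at 5.46 and the ubiquitin ligase gene Rnf183 at 5.26.

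Among the falls, Ptn, coding for the heparin-binding growth factor pleiotrophin, had a control signal of 6170 and a log2 change of -8.21 ± 0.47 (1416211_a_at, adjusted p = 6.87e-05). The neuropeptide gene Vip fell (-7.99, 5657 to 15.4), the small leucine-rich proteoglycan gene Ogn (-7.81, 4209 to 10.0), Vgll3, a cofactor of TEAD transcription factors, (-7.32), and Mfap5, a microfibril component, (-7.29, 4220 to 18.1). Cd24a had -6.61, the proteoglycan gene Prelp -6.51, the pentraxin gene Ptx3 -6.32 (14550 to 177), the actin-binding Ablim1 -6.23, the imprinted growth factor gene Igf2 -5.98, the planar polarity gene Prickle1 -5.93 and the integrin beta subunit gene Itgb5 -5.87. All of these were called.

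The fibroblast and extracellular matrix markers were lower as a list, with a mean log2 change of -1.67 (adjusted p = 0.000355, 5.43e-16 to 0.0227 over the alternatives with the correlation held, adjusted p = 0.228 with an estimated correlation). Of 26 tested members, 12 fell and 1 rose, or 14 and 2 when adjusted over the list alone. Col1a1 went from 23290 to 524 (1423669_at, -5.50), and Postn, the periostin gene, from 3406 to 67.7 (-5.50), while Col1a2 had -0.64 (36060 to 23210, adjusted p = 0.178) and Dcn 0.41 (13830 to 18420, adjusted p = 0.224). YAP and TGF-beta target genes averaged -1.61, with 10 of 18 falling and 3 rising, both over all genes and adjusted over the list alone (adjusted p = 0.0207, range 3.35e-11 to 0.162, adjusted p = 0.803 with an estimated correlation). They included Thbs1, thrombospondin (-5.19), Ltbp2, a latent TGF-beta binding protein (-4.33), Amotl2 (-3.66) and Id2, an inhibitor of DNA binding (-3.65).

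Interferon-stimulated genes averaged -0.74, and 6 of 30 fell and 0 rose, 7 adjusted over the list alone (adjusted p = 0.0111, range 0.000701 to 0.0664, adjusted p = 0.871 with an estimated correlation). Samd9l fell (-1.93), Rtp4 (-1.75), Trim30a (-1.49) and Irgm1 (-1.30). Hypoxia and glycolysis genes averaged 0.38, with 8 of 27 rising and 2 falling, 11 and 3 adjusted over the list alone (adjusted p = 0.0111, range 0.000426 to 0.0992, adjusted p = 0.871 with an estimated correlation). Ankrd37 rose by 4.30, the prolyl hydroxylase gene Egln3 by 1.64 and Bnip3, coding for a mitochondrial mitophagy protein, by 1.60, whereas the vasodilator peptide gene Adm fell (-4.42). With the 4 NIH3T3 arrays alone, the calls of Samd9l (adjusted p = 0.106), Rtp4 (0.0692), Egln3 (0.0757), Adm (0.0802), Trim30a and Irgm1 were lost, and those of Ankrd37 and Bnip3 were not.

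Members of other lists moved in NIH3T3 without a call of the list. The immediate early genes had 8 rising and 2 falling of 23 (adjusted p = 0.381), with the phosphatase gene Dusp6 at 2.46, Egr3 at 1.92, Ier3 at 1.82 and Jun at 1.80. Of 32 growth factor, receptor and oncogene list members, 8 rose and 6 fell (adjusted p = 0.703), the falls including the fibroblast growth factor gene Fgf7 (-3.78) and the neuregulin gene Nrg1 (-3.28). The p53 target list averaged -0.65, with 4 of 23 falling and 2 rising (adjusted p = 0.0756, range 0.0237 to 0.371, with the list called in 3 of 15 alternatives), led by the death receptor gene Fas (-4.69), the kinase gene Plk2 (-3.09), Btg2 (-1.76) and Sesn1 (-1.49). G1/S and DNA replication genes had 2 rising and 4 falling of 33 (adjusted p = 0.703), where the cyclin gene Ccnd1 rose by 1.34 and the licensing factor gene Cdt1 by 0.76, and Pole (-0.61) and Mcm7 (-0.54) fell. Of 14 alternatives, the call held in 14 for Ccnd1, 7 for Cdt1, 4 for Pole and 10 for Mcm7. The smallest falls among them were -0.22 for Pole and -0.14 for Mcm7. Adjusted over the list alone, 8 rose and 3 fell of the immediate early genes, 9 and 10 of the growth factors, 3 and 8 of the p53 targets and 2 and 7 of the G1/S genes. Of 32 G2/M and mitosis genes, 5 fell and 0 rose, 5 and 1 adjusted over the list alone (adjusted p = 0.122), among them Kif20a (-0.77), Cenpf (-0.70), Ttk (-0.69) and Kif23 (-0.64). The mean of that list was above 0, at 0.17, under the spike scaling, while under quantile normalization the list was called lower (mean -0.26, adjusted p = 0.0202, range 0.0202 to 0.682).

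Mesenchymal and epithelial transition genes split, 6 rising and 4 falling of 28 (adjusted p = 0.777), with the cadherin gene Cdh11 at -5.04, Tagln at -2.93, the integrin gene Itgb3 at 3.62 and Tgfbi at 2.23. Matrix proteases and their inhibitors had 4 rising and 8 falling of 28 (adjusted p = 0.773), where Adamts5 fell (-3.70), the inhibitor gene Timp3 (-2.31), the lysyl oxidase gene Lox (-2.28) and Adam12 (-1.98). Among 20 metastasis suppressors 1 rose and 4 fell (adjusted p = 0.703), with the anchoring protein gene Akap12 at -4.14, Pdcd4 at -1.75, the caveolin gene Cav1 at -1.41 and the ribonucleotide reductase gene Rrm1 at -0.43. The Rrm1 call held in 5 of 14 alternatives, with a smallest fall of -0.04. Of 19 chemokines and adhesion genes 4 rose and 3 fell (adjusted p = 0.795), with Ccl8 at 3.72, Cxcl5 at -5.00 and Vcam1 at -3.59 besides Il33. Adjusted over the list alone, 7 rose and 6 fell of the mesenchymal genes, and the counts of the other 3 lists were as over all probe sets.

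The lists closest to the known role of PGC7 were not called in NIH3T3. DNA methylation machinery had a mean of -0.39, with 1 of 22 rising and 3 falling (adjusted p = 0.281): Gadd45a rose by 2.18, and Gadd45b (-2.95), Gadd45g (-2.01) and the chromatin remodeller gene Hells (-0.92) fell. The methyltransferase genes had -0.11 (Dnmt1, adjusted p = 0.615), -0.18 (Dnmt3a) and -0.76 (Dnmt3b, adjusted p = 0.0903), and Uhrf1 had -0.25. Imprinted genes had 2 rising and 5 falling of 22 (adjusted p = 0.703), among them Slc22a18 at 4.88, Slc38a4 at -3.76 and Peg3 at -3.14. Of 4 tested germline genes, Brdt (1.75) and Tdrd7 (0.83) rose, Cpeb1 (-1.45) fell and Tex11 went uncalled from 1.67 to 293 ± 247 (adjusted p = 0.0577). Pluripotency genes had 0 called of 6 (adjusted p = 0.777), the largest value being 2.39 for Dppa2. Adjusted over the list alone, 3 imprinted genes rose and 5 fell, and 3 germline genes rose and 1 fell. The X-linked germline gene Rhox5 had a high signal throughout, 19260 in the control and 20020 in the PGC7 arrays.

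Antigen presentation genes had 2 falling of 15 (adjusted p = 0.703), H2-M3 (-2.11) and Erap1 (-1.25). The stress response list had 1 falling of 27, Phgdh at -0.67 (adjusted p = 0.777), and cholesterol synthesis 0 called of 19 (adjusted p = 0.777). Of 20 oxidant and heat stress genes 1 rose and 2 fell (adjusted p = 0.703): Srxn1 (1.05), Gstm1 (-1.66) and Osgin1 (-1.06). Melanocyte markers had 2 rising and 1 falling of 24 (adjusted p = 0.703), with Gpnmb at 4.83 and Erbb3 at 1.27. Macrophage genes had Cd14 rising (1.92) among 8 (adjusted p = 0.235), neuronal genes Snap25 (2.28) among 7 (adjusted p = 0.777), skeletal muscle genes Chrna1 (3.82) and Mef2c (-1.50) among 14 (adjusted p = 0.777). The adipocyte genes Lpl (-4.61) and Scd1 (0.73) were called among 6 (adjusted p = 0.777), and the cartilage and bone genes Mgp (-5.45) and Phex (2.19) among 7 (adjusted p = 0.795). The epithelial list had 0 called of 7 (adjusted p = 0.777), the endothelial genes 0 of 3, and housekeeping genes 2 of 14 rising, Ywhaz (0.77) and Tfrc (0.46) (adjusted p = 0.777). Adjusted over the list alone, 4 rose and 3 fell of the oxidant and heat stress genes, 1 and 2 of the antigen presentation genes, 2 and 0 of the macrophage genes, 1 and 1 of the neuronal genes, 1 and 2 of the adipocyte genes and 2 and 2 of the cartilage genes. Mean, median and test differed in sign for the pluripotency, protease, cartilage, chemokine, growth factor, oxidant and housekeeping lists.

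X-linked genes, a group outside the fixed lists and compared without a test, had lower median changes in NIH3T3 PGC7 arrays than other genes. Over 354 such genes the median change from the control was -0.77 in the uncloned array, -0.23 in clone 1 and -0.25 in clone 2, against -0.02 to -0.04 for other genes, and 0.06 to 0.10 in the B16F10 clones. The spread of neighbouring-gene medians along the chromosomes was 1.61 times or more the highest of 200 shuffled orders in each NIH3T3 PGC7 array.

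In B16F10 genes of the integrated stress response, Nupr1, Trib3, Ddit4, Chac1 and Sesn2 (called in 9 of 13 alternatives), were strongly higher in the PGC7 clones, and the hypoxia and immediate early lists were higher. With an estimated correlation 0 of the 8 list calls in this line held (adjusted p = 0.525 to 0.791). The homeobox gene Rhox5 and the class I heavy chain genes H2-K1 and H2-D1 were higher. Cyclin D1, the ETS factor Etv5 and several small nucleolar RNA host genes were lower, and so were cell cycle genes as groups (adjusted p = 0.707 and 0.765 with an estimated correlation). The number called was 300, with 233 higher (173 genes) and 67 lower (49 genes). Without the uncloned NIH3T3 array, which enters the shared spread, 1835 were called, and 2196 with the B16F10 arrays alone. Without NIH3T3 clone 1 or 2 the count was 140 and 184, and without B16F10 clone 1, 2 or 3 it was 65, 138 and 59. At least 2-fold in all 3 clones were 710, of which 585 were higher (203 of 1227 under the spike scaling, which turned the balance), and 186, 198 and 291 with clone 1, 2 or 3 in the control's place.

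Nupr1 (1419665_a_at), a stress-induced transcription cofactor gene, rose from 178 to 4218 ± 747 (log2 4.49 ± 0.20, adjusted p = 0.000153). Rhox5 (1423429_at) rose from 54.0 to 1173 ± 213 (4.21 ± 0.21, adjusted p = 0.000237), and the pseudokinase gene Trib3 from 126 to 2170 (4.01). The class I heavy chain gene H2-K1 rose by 3.92 at probe set 1427746_x_at (1.67 to 159) and by 1.09 at its brightest probe set 1451931_x_at (620 to 1337). Others that rose were Hebp1, a heme-binding protein gene (3.41), Kdelr3, coding for a receptor that returns proteins to the endoplasmic reticulum (3.30), the immediate early transcription factor gene Egr1 (3.23, 303 to 2943), the DNA repair gene Brca1 (3.22), the mTORC1 inhibitor gene Ddit4 (3.15, 512 to 4764), Art5 (3.04), the leukocyte integrin beta subunit gene Itgb2 (3.03, 1.73 to 79.6) and the cytochrome gene Cyp4v3 (2.98). Of the other Brca1 probe sets, 1427698_at had 0.01 (adjusted p = 0.995) and a pair of others rose by 1.89 and 2.36. The call of Cyp4v3 held in 8 of 13 alternatives, that of Art5 in 9 of 13 and that of Itgb2 in 10 of 13. That of H2-K1 at 1451931_x_at held in 10 of 14. Those of Nupr1, Rhox5, Trib3, Hebp1, Kdelr3, Egr1, Ddit4 and Brca1 held in all in which they passed the filter.

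Etv5, an ETS transcription factor gene, fell from 784 to 124 (1428142_at, -2.62 ± 0.27, adjusted p = 0.00581). The receptor-modifying Ramp3 fell (-2.36), the growth factor receptor regulator gene Lrig1 (-1.92), the actin-binding Lasp1 (-1.90, 7063 to 1884), Zcchc24 (-1.89), and Ccnd1 (-1.66, 1448698_at, 2458 to 775). The host genes Snhg3 (-1.84, 1793 to 499), Snhg5 (-1.60, 2932 to 961) and Snhg17 (-1.26), the nucleolin gene Ncl (-1.43) and the biglycan gene Bgn (-1.37, 23.9 to 3.81) fell as well. Probe sets of the same gene pointed the other way, uncalled, for Lrig1 (0.35), Lasp1 (0.61 and 0.56), Zcchc24 (1.03) and Bgn (0.49). The 4 other Ncl probe sets were lower but uncalled (-0.15 to -1.18), and the Ncl call held in 8 of 14 alternatives and that of Bgn in 6 of 14. The Snhg17 call held in 5 of 13, that of Lrig1 in 6 of 14, Ramp3 in 8, Snhg5 in 9, Zcchc24 in 11 and Snhg3 in 12 of 14. Those of Etv5, Lasp1 and Ccnd1 held in all 14.

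**Figure D2:**
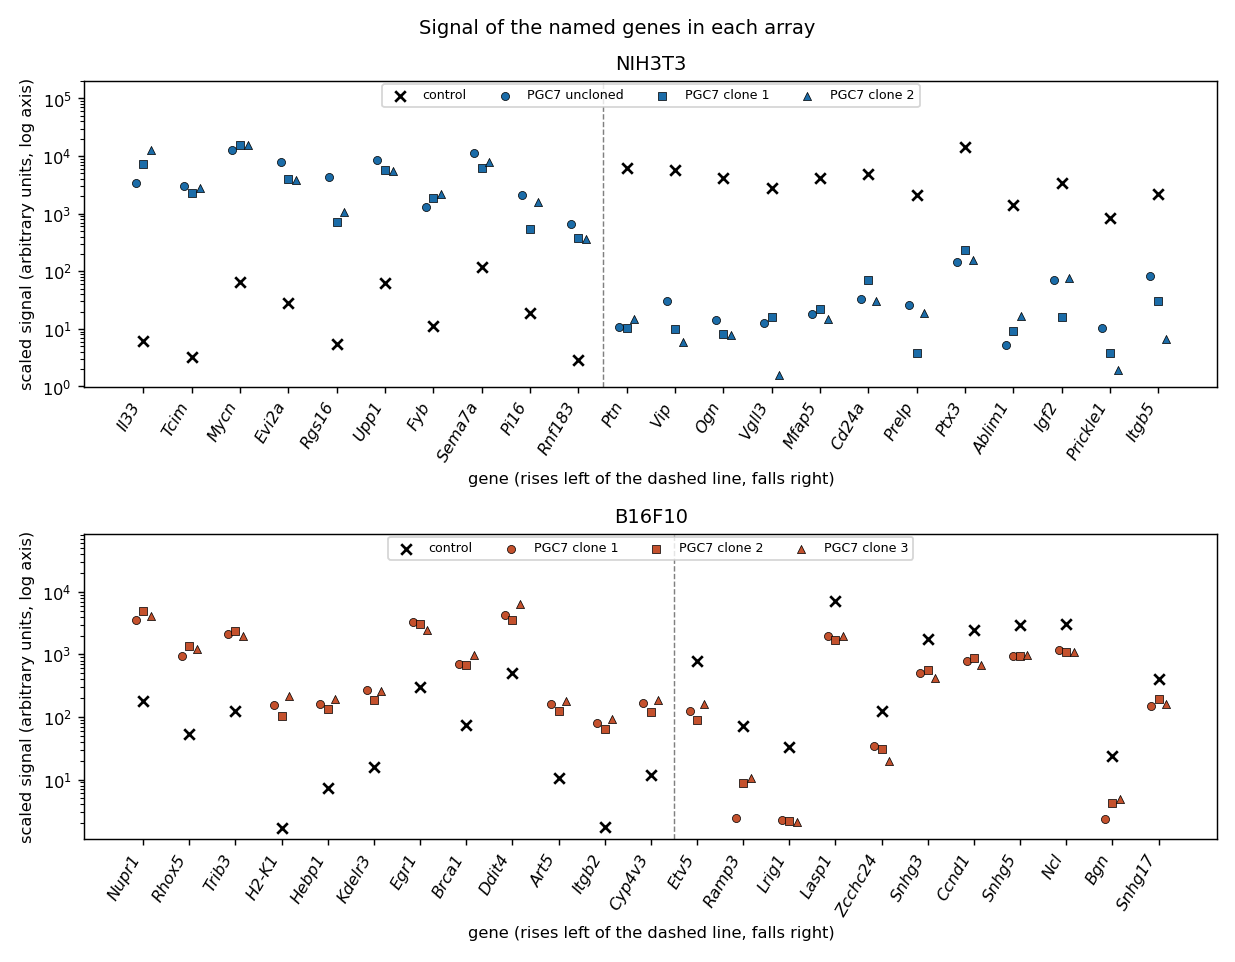
Scaled signal (vertical axis, log scale) of genes with the largest rises and falls in NIH3T3 and in B16F10 (horizontal axis), with the control as a cross and each PGC7 array as a point. Rises stand left of the dashed line and falls right of it, and the NIH3T3 changes are the larger.

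The unfolded protein and integrated stress response list had a mean of 1.18, with 10 of 27 rising and 0 falling, 16 and 1 adjusted over the list alone (adjusted p = 5.88e-08, range 1.98e-19 to 6.00e-06, adjusted p = 0.525 with an estimated correlation). Chac1, a glutathione-degrading enzyme gene, rose by 2.88 (called in 14 of 14 alternatives) and Sesn2 by 2.01 (9 of 13). Of genes chosen after their values were seen, the asparagine synthetase gene Asns (1.65, adjusted p = 0.014) and Ddit3 (1.15, adjusted p = 0.0365) rose, while the endoplasmic reticulum chaperone genes Hspa5 (-0.06, adjusted p = 0.853) and Hyou1 (-0.29, adjusted p = 0.425) were not called. Hypoxia and glycolysis genes averaged 0.82, with 3 of 27 rising and 10 adjusted over the list alone (adjusted p = 1.24e-05, range 2.76e-10 to 0.000483, adjusted p = 0.765 with an estimated correlation). Under the spike scaling the means of the stress, hypoxia and immediate early lists were 0.55, 0.18 and 0.22, and all 3 stayed called. Bnip3 rose by 1.92, Vegfa by 1.85 and the oxidoreductase gene Ero1a by 1.80, and Car9 had 3.13 (adjusted p = 0.147). Of 14 alternatives, the call held in 8 for Bnip3, 11 for Vegfa, 12 for Ero1a and, among immediate early genes, 10 for Atf3 and 13 for Jun. Immediate early genes averaged 0.79, with 5 of 23 rising and 8 adjusted over the list alone (adjusted p = 0.000194, range 1.44e-08 to 0.00867, adjusted p = 0.525 with an estimated correlation), including Egr2 (2.97), Atf3 (2.21) and Jun (1.57).

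Cell cycle lists were lower with few members called singly. G2/M and mitosis genes averaged -0.28 with 0 of 32 called, or 4 falling adjusted over the list alone (adjusted p = 4.39e-07, range 1.14e-07 to 0.00038, adjusted p = 0.707 with an estimated correlation). Their mean was -0.94 under the spike scaling. Kif23 and Cdc20 had -0.61 each (adjusted p = 0.0702 and 0.0934), Anln -0.57 and Plk1 -0.51. G1/S and DNA replication genes averaged -0.23, and of 33 only Ccnd1 fell, also adjusted over the list alone (adjusted p = 0.00129, range 0.000197 to 0.00787, adjusted p = 0.765 with an estimated correlation). YAP and TGF-beta target genes averaged -0.45, with 0 of 18 called and 1 falling adjusted over the list alone (adjusted p = 0.0251, range 0.000764 to 0.0641, adjusted p = 0.525 with an estimated correlation), as in Ccn2 (-1.31, adjusted p = 0.375) and Ajuba (-0.98, adjusted p = 0.0969).

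Cholesterol synthesis genes averaged 0.46 but -0.19 under the spike scaling, with 1 of 19 rising, Msmo1 at 1.08, and 4 adjusted over the list alone (adjusted p = 0.00221, range 0.000257 to 0.0337, adjusted p = 0.791 with an estimated correlation). Melanocyte markers averaged 0.64 but -0.0037 under the spike scaling, with 1 of 24 rising, the channel gene Trpm1 at 2.15, and 3 adjusted over the list alone (adjusted p = 0.00641, range 6.73e-05 to 0.0428, adjusted p = 0.765 with an estimated correlation). Kit had 2.98 (adjusted p = 0.0925) and Oca2 1.69 (adjusted p = 0.118). The call of Trpm1 held in 5 of 14 alternatives and that of Msmo1 in 6 of 14. The poly-A spikes themselves averaged 0.59 above the control in these clones.

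**Figure D3:**
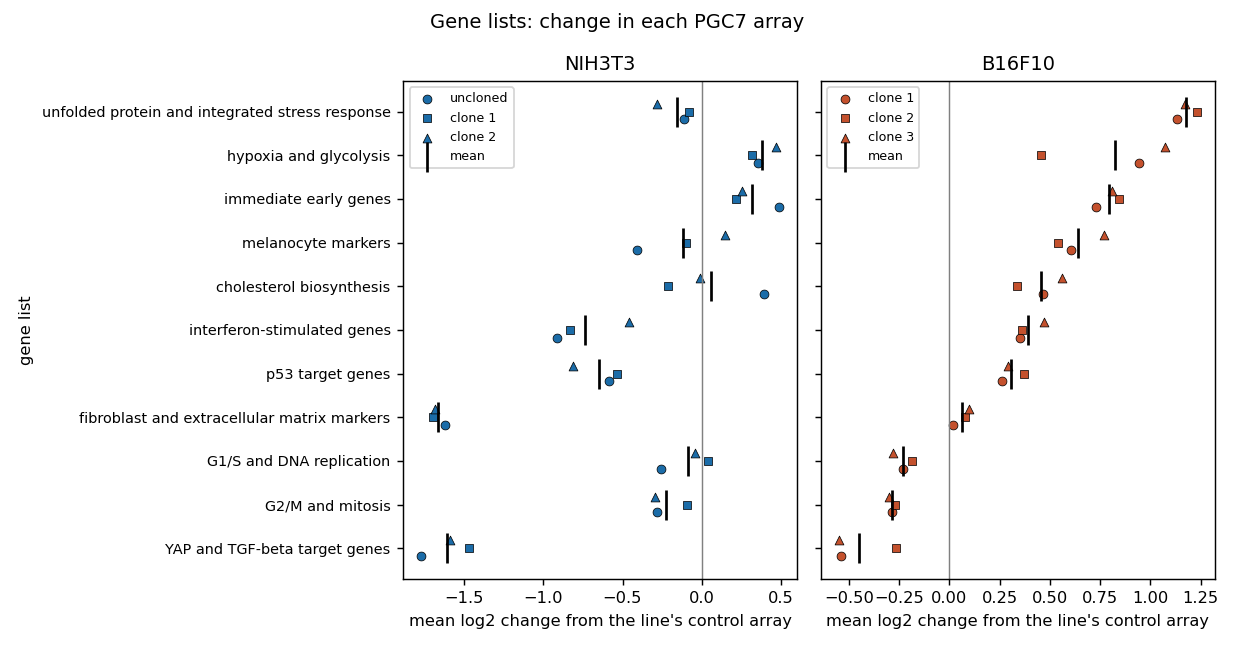
Mean log2 change from the line's control (horizontal axis) of 11 gene lists (vertical axis) in each PGC7 array of NIH3T3 and B16F10, with a tick at the mean of 3. Stress and hypoxia lists lie right of 0 and cell cycle lists left of it in every B16F10 clone, though under spike scaling the cholesterol and melanocyte means in B16F10 were -0.19 and -0.0037 and the NIH3T3 G2/M mean 0.17.

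Other lists were not called in B16F10. Antigen presentation had 2 of 15 rising, H2-D1 (1.20, 816 to 1895) and H2-K1, whose calls at the brightest probe sets were lost under the spike scaling (adjusted p = 0.300 and 0.406). That list had an adjusted p of 0.178 (range 0.0336 to 0.406). Interferon-stimulated genes had 0 of 30 called (adjusted p = 0.0768, range 0.00682 to 0.168, with the list called in 7 of 15 alternatives, higher with quantile normalization at a mean of 0.44 and as deposited at 0.53), with Rsad2 at 1.61 (adjusted p = 0.23). Of 20 metastasis suppressors, Pdcd4, a translation inhibitor gene, rose by 1.65 (adjusted p = 0.0768, range 0.0202 to 0.0968, with the list called in 4 of 15 alternatives). Among p53 targets Sesn2 and Trp53inp1 (1.44) rose (adjusted p = 0.103, range 0.0362 to 0.181). So did, among oxidant and heat stress genes, the cystine transporter gene Slc7a11 (2.74, adjusted p = 0.168), among proteases Plat (2.15) and Reck (0.94) (adjusted p = 0.55), and among growth factors and receptors Vegfa and Met (1.04), with Ccnd1 falling (adjusted p = 0.847). Of 14 alternatives, the call held in 5 for Reck, 6 for Trp53inp1, 8 for Met and 10 for Plat, and that of Slc7a11 held in 9 of 13. The matrix protein gene Sparc fell (-1.17) in the mesenchymal list (adjusted p = 0.995), and Bgn fell and Fbln5 rose (0.77) among fibroblast markers (adjusted p = 0.828). DNA methylation machinery had 0 of 22 called and a mean of -0.03 (adjusted p = 0.446), and imprinted genes (adjusted p = 0.870), pluripotency genes (adjusted p = 0.729, range 0.00502 to 0.937) and the germline genes likewise had 0 called. Adjusted over the list alone, more were called in B16F10 among p53 targets (5 rose and 1 fell), metastasis suppressors (4 and 0), proteases (4 and 3), oxidant and heat stress genes (3 and 6), antigen presentation (3 and 0), fibroblast markers (1 and 3), growth factors (2 and 2), pluripotency genes (1 and 0) and muscle genes (0 and 1). Over all probe sets 0 were called of the epithelial (adjusted p = 0.870), macrophage (0.852), neuronal (0.995), muscle (0.828), adipocyte (0.857), cartilage (0.746), chemokine (0.290, range 0.00894 to 0.815) and housekeeping (0.857) lists.

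In the test across both lines, 4 lists were called higher, among them hypoxia and immediate early genes, and 4 lower, among them mitosis genes and YAP and TGF-beta targets. With an estimated correlation 0 of these 8 lists were called (adjusted p = 0.540 for each of those named). The immediate early and mitosis lists lost their calls without the B16F10 control, where the change comes from NIH3T3 alone. Genes called across both included Jun (called in 13 of 13 alternatives) and Atf3 (4 of 13), which code for AP-1 family factors. The matrix genes Sparc (12 of 13) and Bgn (7 of 13) were called as well. The number called across both was 39 probe sets, 32 higher (24 genes) and 7 lower (6 genes), from a test for a shift of the same size in both, and 119 of 285 were higher under the spike scaling. It was 7 and 8 without NIH3T3 clone 1 or 2, and 8, 14 and 5 without B16F10 clone 1, 2 or 3. It was 292 without the NIH3T3 control and 3220 without the B16F10 control, but these fits take the change from the other line alone. With the mean of the lines' contrasts it was 1868, and without the intensity trend 5.

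Itgb2 (1450678_at) rose by 3.58 (adjusted p = 0.00883), the GTP cyclohydrolase gene Gch1 by 3.07, Jun by 1.94, the calcium-activated potassium channel gene Kcnn4 by 1.92, Mfap3l by 1.86, Atf3 by 1.85, Tmcc3 by 1.79 and Bnip3 by 1.76. In B16F10 the signals of Kcnn4 (2.80 to 38.6), Mfap3l (2.25 to 30.4), Tmcc3 (1.07 to 26.7) and Bgn (23.9 to 3.81) were under 49.3. With the median as pseudocount these calls and that of Itgb2 were lost (adjusted p = 0.0625 to 0.125). Alternatives counted here leave out the prior without the intensity trend, the mean of the contrasts and the fits without a control. The call of Jun held in 13 of 13 alternatives, that of Sparc in 12 of 13 and that of Itgb2 in 10 of 12. Those of Bnip3, Bgn, Kcnn4 and Tmem158 held in 7 of 13, those of Mfap3l and Gask1b in 6 of 13 and that of Gch1 in 6 of 12. Those of Atf3 and Dkc1 held in only 4 of 13, and those of Tmcc3 and Tmem109 in only 2 each. Bgn fell (-1.61), Tmem158 (-1.14, 0.24 at a second probe set, uncalled), Sparc (-1.12), Tmem109 (-0.97), Gask1b (-0.80) and the dyskerin gene Dkc1 (-0.68). Taking each line's calls, 37 probe sets were higher in both where 15.1 would be met if the lines were independent, 9 were lower in both (4.24), 14 were higher in NIH3T3 and lower in B16F10 (4.34) and 18 the reverse (14.7). Over all 25236 probe sets the changes of the lines correlated at 0.06 (rank correlation 0.08), and for single pairs of arrays at 0.01 to 0.11.

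Hypoxia and glycolysis averaged 0.60, with 2 rising and 16 rising and 1 falling adjusted over the list alone (adjusted p = 2.94e-07, range 1.99e-10 to 0.0107, adjusted p = 0.540 with an estimated correlation). G2/M and mitosis averaged -0.25, with 0 called and 5 falling adjusted over the list alone (adjusted p = 2.82e-06, range 1.65e-07 to 0.119, adjusted p = 0.540 with an estimated correlation). Immediate early genes averaged 0.56, with 2 rising and 6 adjusted over the list alone (adjusted p = 0.0022, range 6.80e-06 to 0.382, adjusted p = 0.540 with an estimated correlation). YAP and TGF-beta targets averaged -1.03, with 0 called but 8 falling and 1 rising adjusted over the list alone (adjusted p = 0.00365, range 2.69e-10 to 0.0282, adjusted p = 0.540 with an estimated correlation). The others were G1/S genes at -0.16 (adjusted p = 0.0106, range 0.00145 to 0.715, adjusted p = 0.83 with an estimated correlation) and stress response at 0.51 (adjusted p = 0.0117, range 5.24e-08 to 0.779, adjusted p = 0.853 with an estimated correlation). Cholesterol synthesis averaged 0.26 (adjusted p = 0.0267, range 0.0019 to 0.779, adjusted p = 0.979 with an estimated correlation) and fibroblast markers -0.80 (adjusted p = 0.0291, range 3.32e-05 to 0.687, adjusted p = 0.853 with an estimated correlation). The stress rise was carried by B16F10 and the fibroblast fall by NIH3T3. The cholesterol, G1/S, immediate early and G2/M lists also lost their calls without the B16F10 control, where the change comes from NIH3T3 alone. Their NIH3T3 means were 0.06, -0.09, 0.32 and -0.22, uncalled there with the main settings. The hypoxia and the YAP and TGF-beta lists kept their calls in all 17 alternatives with the correlation held.

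The lines differed in which genes moved. The largest NIH3T3 changes had little counterpart in B16F10, where several of the genes concerned had almost no signal to lose. A difference was called for 1737 probe sets, 778 with a higher change in NIH3T3 (537 genes) and 959 with a lower one (677 genes), at a median of -0.11. Without the uncloned array this count was 4404, and without B16F10 clone 1, 2 or 3 it was 739, 974 and 780. The differences were 8.50 for Il33 (adjusted p = 0.0024), 7.84 for Evi2a, 7.12 for Tcim, 6.89 for Mycn and 6.47 for Upp1, and -8.12 for Ptn, -8.03 for Vip, -7.55 for Mfap5, -7.41 for Ablim1 and -6.84 for Ogn. In the B16F10 control the signals of Ptn (3.01), Vip (9.47), Mfap5 (6.88) and Ogn (13.1) were near the floor, so a fall of these genes could not be seen there.

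Of the 32 probe sets called in opposite directions, those of 6 genes chosen after their values were seen are Ccnd1 (1.54 in NIH3T3 and -1.66 in B16F10 at 1448698_at), Etv5 (1.90 and -2.62), Lrig1 (2.00 and -1.92), Pdcd4 (-1.75 and 1.65), Fbln5 (-4.08 and 0.77) and the protease inhibitor gene Reck (-1.39 and 0.94). Of 14 alternatives, the B16F10 call held in 14 for Ccnd1 and Etv5, 13 for Pdcd4, 6 for Lrig1 and 5 each for Fbln5 and Reck. Of the list changes, the fibroblast markers differed by -1.73 (adjusted p = 0.000243, adjusted p = 0.241 with an estimated correlation, 10 of 26 lower and 1 higher, 12 and 2 adjusted over the list alone). Of these 26, 18 had a B16F10 control signal under 49.3 and little to lose there; the 7 above it in both controls differed by -1.96. Stress response genes differed by -1.34 (adjusted p = 0.000243, adjusted p = 0.771 with an estimated correlation, 12 of 27 lower, 17 lower and 2 higher adjusted over the list alone). Interferon-stimulated genes differed by -1.13 (adjusted p = 0.00105, adjusted p = 0.771 with an estimated correlation, 3 of 30 lower, 7 adjusted over the list alone). The p53 targets differed by -0.95 (adjusted p = 0.0361, adjusted p = 0.853 with an estimated correlation, 5 of 23 lower and 1 higher, 6 and 1 adjusted over the list alone), and under the spike scaling by 0.02. That scaling also left smaller differences of -0.94 for fibroblast markers, -0.31 for stress response genes and -0.21 for interferon-stimulated genes. It moved the median difference of all tested probe sets to 0.88. Relative to other genes all 4 lists stayed called lower with the correlation held (adjusted p = 2.95e-14, 2.15e-06 and 6.31e-06 in that order, and 0.00254 for p53 targets).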

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

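The tests of chromosome regions as part of the NIH3T3 difference, of array scaling in NIH3T3 and in B16F10, and of markers expressed in both controls, were chosen only after the result was seen.

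The change with PGC7 differed between the lines for 1737 probe sets by a test of the difference itself, and the following named genes and lists passed it. The differences (NIH3T3 change minus B16F10 change, log2) were 8.50 for Il33, 7.84 for Evi2a, 7.12 for Tcim, 6.89 for Mycn, 6.47 for Upp1, -8.12 for Ptn, -8.03 for Vip, -7.55 for Mfap5, -7.41 for Ablim1 and -6.84 for Ogn. For lists they were -1.13 (interferon-stimulated genes), -0.95 (p53 targets), -1.73 (fibroblast and matrix markers) and -1.34 (stress response), each lower in NIH3T3. Under the spike scaling they were -0.21, 0.02, -0.94 and -0.31, while the median difference of all tested probe sets was 0.88. Relative to other genes all 4 lists stayed called lower there with the correlation held. Ptn, Vip, Mfap5 and Ogn had signals of 3.01 to 13.1 in the B16F10 control, so a fall there could not be seen. Of the 26 fibroblast markers, 18 were under 49.3 in that control and had little to lose, though Bgn among them was called lower there. The 7 above it in both controls differed by -1.96. All 10 genes were called in every alternative followed for single genes in which they passed the filter (13 for 6 genes, 12 for Ptn, Vip and Mfap5, 10 for Ogn). The prior without the intensity trend was not among these. With an estimated inter-gene correlation 0 of the 4 lists passed. Since line and array batch cannot be told apart, no test was made of levels between the lines, only of this difference in change. The poly-A spikes, used here only for an alternative scaling, were higher in the B16F10 PGC7 arrays than in the control by a mean of 0.59 (0.58, 0.47 and 0.72 in clones 1, 2 and 3); no explanation of it was tested.

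The NIH3T3 control stood apart from the PGC7 arrays at 2168 probe sets, against 542 or fewer for any PGC7 array. Chromosome gains or losses as wide as a window of 50 genes are unlikely to account for the whole of it. After the median of each neighbourhood was subtracted, 897 of 932 genes (96.2%) stayed at least 2-fold in all 3 arrays, against 257 at most with a PGC7 array in the control's place. Window medians moved little, with 0 of 222 shifted by a log2 of 0.5 or more in all 3 arrays. Gains or losses smaller than a window are not removed by this subtraction and were not tested. Array scaling as the whole cause is argued against by 1957 probe sets with the values as deposited and 2184 with quantile normalization. Gains or losses as part of it cannot be told apart from regional regulation: neighbourhood medians spread at least 1.61 times the highest of the shuffled orders in every PGC7 array against control, but also 2.09 and 2.02 times for the uncloned array against clones 1 and 2. An effect of PGC7, of the infection and of differing culture histories stay open, with 1 control and no test that separates them.

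In B16F10 the stress, hypoxia and immediate early lists were higher and the cell cycle lists lower. With an estimated correlation none of these calls held (adjusted p = 0.525 for the stress and immediate early lists, 0.765 for hypoxia and G1/S, 0.707 for G2/M). The stress list's mean was 1.13, 1.23 and 1.17 in clones 1, 2 and 3. Its adjusted p was at most 1.49e-07 without each clone in turn, with the correlation held. Both argue against a deviating clone for that list. The hypoxia, immediate early, G1/S and G2/M lists also stayed called without each clone in turn, with the correlation held. Over all alternatives with it held, their adjusted p was at most 0.000483, 0.00867, 0.00787 and 0.00038. This argues against 1 deviating clone for these calls too. The hypoxia means were 0.94, 0.45 and 1.07. Under quantile normalization the adjusted p was at most 2.03e-06 for the stress and G2/M lists. This cannot exclude array scaling, since the list test compares members with other genes and a shift of all genes largely cancels. On the spikes the stress mean was 0.55, the G2/M mean -0.94 and 15.3% of called probe sets were higher, against 77.7%. The growth state of the 1 control culture may account for the pattern in place of PGC7, and the pair cannot be told apart because only 1 such culture was measured. The stress list's adjusted p ranged from 1.98e-19 to 6.00e-06 over the alternatives with the correlation held.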

How the results depend on the processing

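The values as deposited and the poly-A spike scaling were chosen only after the data were seen; the other alternatives were fixed before the data were examined. No paired analysis was possible because clone numbers are not carried by the controls. Without a line's only control, values across both lines rest on the change in the other line alone. All 100 NIH3T3, 45 B16F10, 14 shared and 10 differing named genes kept their direction in each alternative followed for single genes in which they passed the filter. Of them, 57, 17, 1 and 10 kept their call in all of these, and 19, 25, 12 and 0 lost their call without 1 array. The prior without the intensity trend was not followed for single genes. Across both lines, neither were the mean of the contrasts and the fits without a control. All 4 NIH3T3 lists, 6 of 8 in B16F10 and 6 of 8 across both kept their direction. For NIH3T3, 3229 became 1151 with only its 4 arrays, 2127 without the intensity trend and 2093 as deposited (37.7% higher, against 50.6%, and 74.7% of 2224 on the spikes). Leaving out a PGC7 array gave 1999 (without B16F10 clone 1) to 6133 (without the uncloned array). For B16F10, 300 became 199 with quantile normalization, 177 without a filter, 2196 with only its 4 arrays, 70 without the trend, 197 as deposited and 588 on the spikes (15.3% higher, against 77.7%), and 59 to 1835 without 1 array: 65, 138 and 59 without B16F10 clones 1, 2 and 3, and 1835, 140 and 184 without the uncloned array and NIH3T3 clones 1 and 2. Across both, 39 became 81 with the stricter filter, where fewer probe sets were tested, 5 without the trend, 1868 for the mean of the contrasts, 292 and 3220 without the NIH3T3 and B16F10 controls, 16 as deposited, 285 on the spikes (41.8% higher), and 5 (without B16F10 clone 3) to 32 without 1 array (7 and 8 without NIH3T3 clones 1 and 2, 8 and 14 without B16F10 clones 1 and 2). The difference between the lines, 1737, became 934 without the trend, 927 as deposited, 3386 on the spikes (91.3% higher, against 44.8%), and 739 to 4404 without 1 array (739, 974 and 780 without B16F10 clones 1, 2 and 3, 4404 without the uncloned array). The 4 NIH3T3 lists became 2 with the stricter filter and 0 with an estimated correlation (4 to 6 without 1 array), the 8 in B16F10 0 with it and 12 on the spikes (7 to 10), the 8 across both 0 with it and 4 without the B16F10 control (6 to 9). At least 2-fold in NIH3T3, 2168, became 3799 without a filter and 872 with the stricter one (2168 to 3213 without 1 array), and in B16F10, 710 became 1070 with pseudocount 1, 271 with the median, 1410 without a filter, 244 with the stricter one, 1227 on the spikes (16.5% higher), and 710 to 1182 (without clone 2). The correlation of the lines stayed at 0.04 to 0.08 without 1 array. Reversed means were 0.028 for fibroblast markers across both without the NIH3T3 control, -0.16 for stress genes without the B16F10 control and, on the spikes in B16F10, -0.0037 for melanocyte and -0.19 for cholesterol genes, both still higher than other genes (adjusted p = 0.000131 and 0.0337, ranges 6.73e-05 to 0.0428 and 0.000257 to 0.0337), and -0.18, -0.17 and -0.13 for the interferon, metastasis suppressor and chemokine lists, uncalled before and there called higher relative to other genes. Filters change the number of probe sets tested; for the other moved values the cause was not tested. Low signals limit the changes measured, as the pseudocounts show in B16F10.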

Other observations

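All tests in this part were chosen only after the result was seen.

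Rhox5, an X-linked germline gene known to be kept silent by DNA methylation, rose in all 3 B16F10 clones. If silencing were lost at germline genes as a group, other members might rise with it. Rhox5 itself was left out of the count. In B16F10, 2.22% of the 45 other measured germline and X-linked germline genes were at least 2-fold higher in all 3 clones (Nxf3) and 0 were lower, against 3.96% higher among genes of like signal. In NIH3T3, 4.44% were higher (Brdt and Tex11) against 4.81%, and 6 genes were lower. With 95% binomial intervals of 0.0562% to 11.8% and 0.543% to 15.1%, a criterion added after the shares were seen, a loss over the group and its absence cannot be told apart in either line. Methylation was not measured here.

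Several Snhg genes, which host small nucleolar RNAs and whose spliced transcripts are decayed when translated, stood among the largest falls in B16F10. The hypothesis that they fell as a group was put to the 9 tested members outside the named ones: 9 of 9 were below 0, with a mean of -0.54 and a camera p of 0.000332 (0.0235 with an estimated correlation). None of the 9 was called singly (adjusted p = 0.0655 to 0.919). In NIH3T3, where no such test was made, 5 of the 9 were below 0, including Snhg1 (-0.84), Snhg4 (-0.88), Snhg12 (-0.71) and Snhg8 (-0.45). These genes are likely to share regulation, so they are not independent, and nonsense-mediated decay, which stress responses can alter, was not measured.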
